A study of Homo sapiens with 110 samples.

How the data were processed

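The series profiled where RNA-binding proteins sit on chromatin by chromatin immunoprecipitation and sequencing (ChIP-seq) in HepG2, a human liver carcinoma line, and K562, a human chronic myelogenous leukaemia line. The labels list 110 samples, of which 32 are inputs and 78 are immunoprecipitations. A total of 70 peak lists were analysed: 68 single-end lists of 36 proteins, 33 of them from HepG2 and 35 from K562, and 2 paired-end HepG2 lists, of RBM25 and YY1 in cells that the labels call NC. The inputs, the RBM25 and YY1 samples in which the other protein was knocked down, and the SRSF3 and SRSF7 samples of HepG2 were not analysed here. The cell type given for the K562 samples is the same liver carcinoma as for HepG2, so the groups were taken from the cell line label. Every protein was profiled with 1 and the same antibody in both lines, per the labels.

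BWA and MACS2 and the builds GRCh37 and hg19 are named in the submitters' processing notes, without versions. Nuclei were isolated and sonicated before the immunoprecipitation, per the labels' protocols. The authors deposited each list as a narrowPeak table, in which the signal is the peak caller's own value per peak and the score is a whole number from 703 to 1000, as the deposited columns show. The signal of the deposited lists was used only to rank peaks within a list, and the deposited score was not used. The p column holds -1 in every row and was not used. The names of all 70 lists carry an irreproducible discovery rate (IDR) of 0.02, but how it was applied, and the peak caller's own threshold, are not given in the sources used here. The labels of both replicates of an NC sample name the same list, while whether a single-end list joins the 2 replicated experiments that the series' design text mentions is not given in the sources used here. The names of 7 of the lists mark another kind of list than the rest, with a meaning not given in the sources used here. With 1 list per protein and line there was no replicate error, so proteins served as the units of the tests. Proteins share chromatin and are not independent, and p-values measure only the spread between these proteins.

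The lists held 750059 rows. Some intervals occur on several rows, each with its own summit, and 663998 distinct intervals were used for overlaps, shares and odds ratios, each with its highest signal. Numbers of peaks are rows as deposited. Overlap meant at least 1 bp. Coordinates are 1-based and in hg19. Association between lists was measured as the log2 odds ratio over merged regions, with 0.5 added to each cell. Lists of fewer than 100 peaks were left out of the tests on overlap. Sign-flip permutation tests over proteins were two-sided and used 100000 resamples, as did the permutations of protein names. Those for the same protein and for families were one-sided, and those for pairs and for the difference in families between the lines were two-sided. Alternatives with permuted protein names used 10000 resamples. Random placement moved every peak within its chromosome in 100 draws. Shares carry exact Clopper-Pearson intervals at 95%, which cover counting error only, since neighbouring peaks are not independent. Sequencing depth is unknown, because peak lists hold no read counts, and a longer list can reflect a deeper library as well as wider binding.

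Regions bound by more proteins in one line were tested with an exact McNemar test over the 32 proteins with a list in both lines. Both lists of a protein were first shortened to the same number of peaks, those with the highest signal. Benjamini-Hochberg adjustment at 0.05 covered regions with at least 6 discordant proteins. The regions named are the 12 higher in each line with the smallest adjusted p, ties going to the larger difference in the number of proteins, then the larger sum. Named as well are the 10 with the most proteins over both lines, and the 10 with the smallest sum of signal ranks in the RBM25 NC and YY1 NC lists. Every profiled protein could be named.

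Tests, alternatives and the naming rule were fixed before the data were examined, but several needed a gene annotation or a genome of the build of the lists. The gene table used here is of GRCh38.p14, so its coordinates could not be set against hg19. The share of peaks at promoters, the comparison of promoters with distal sites, the test per promoter, the 15 gene lists and the YY1 motif were not made for that reason, and no gene is named for a region. In their place, and chosen after the lists were seen, stand the share of peaks at POLR2G sites, shared peaks at POLR2G sites, the test per merged region, the named regions, and regions without a POLR2G peak. The comparison of autosomes was also added after the lists were seen.

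The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data first. Among 109914 simulated regions, 200 were given fewer proteins in one line. The McNemar test recovered 120 of them with 25% of the proteins kept, with 0 other calls, and 186 with 10% kept, with 1 other call. Without any effect it called 0 regions. Proteins were drawn independently within each simulated region. Real proteins share chromatin, so these counts do not give the error rate on the real lists. In 200 simulated sets without effect, p fell below 0.05 in 5.5% for the sign-flip test, 4.5% for the same protein, 5% for families and 8.5% for pairs, so p-values for pairs are somewhat too small.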

Results

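RNA-binding proteins are known for their work on transcripts, and this series asked where they sit on chromatin. The proteins include serine/arginine-rich splicing factors (SRSF1, SRSF4, SRSF9), heterogeneous nuclear ribonucleoproteins (HNRNPC, HNRNPK, HNRNPL), the U2AF heterodimer that recognises the ends of introns, FET proteins (FUS, TAF15), argonautes and the paraspeckle proteins NONO and SFPQ. POLR2G, a subunit of RNA polymerase II, and GTF2F1, a subunit of the general transcription factor TFIIF, were profiled alongside. HepG2 gave 33 single-end lists with 183 to 42300 peaks (median 5919, 373711 in all), and K562 gave 35 with 18 to 49843 (median 2907, 257078 in all). The paired-end lists held 73517 peaks for RBM25 NC and 45753 for YY1 NC. Each protein, line and experiment had 1 list, and read depth was unknown.

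Most proteins had more peaks in HepG2 than in K562. U2AF2 fell from 1954 peaks in HepG2 to 37 in K562, HNRNPC from 17697 to 501, SRSF9 from 618 to 18 and TAF15 from 14151 to 444. The opposite held for FIP1L1, part of the cleavage and polyadenylation machinery, with 1803 peaks in HepG2 and 7410 in K562, for GTF2F1 (3649 and 11550), for the U1 snRNP protein SNRNP70 (183 and 522) and for the U4/U6 snRNP protein PRPF4 (2433 and 5331). RBM25 was nearly equal, with 42300 and 41509. U2AF1, the partner of U2AF2, had 3236 and 2907 peaks, a ratio of 1.11 where that of U2AF2 was 52.8. Over the 32 proteins with both lists, the mean log2 ratio of HepG2 to K562 was 1.26 (SD 2.05, n = 32), or 2.39-fold. A total of 24 proteins had more peaks in HepG2 and 8 in K562 (two-sided sign-flip permutation p = 0.001). Read depth, which affects how many peaks are called, was unknown for both lines.

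**Figure D1:**
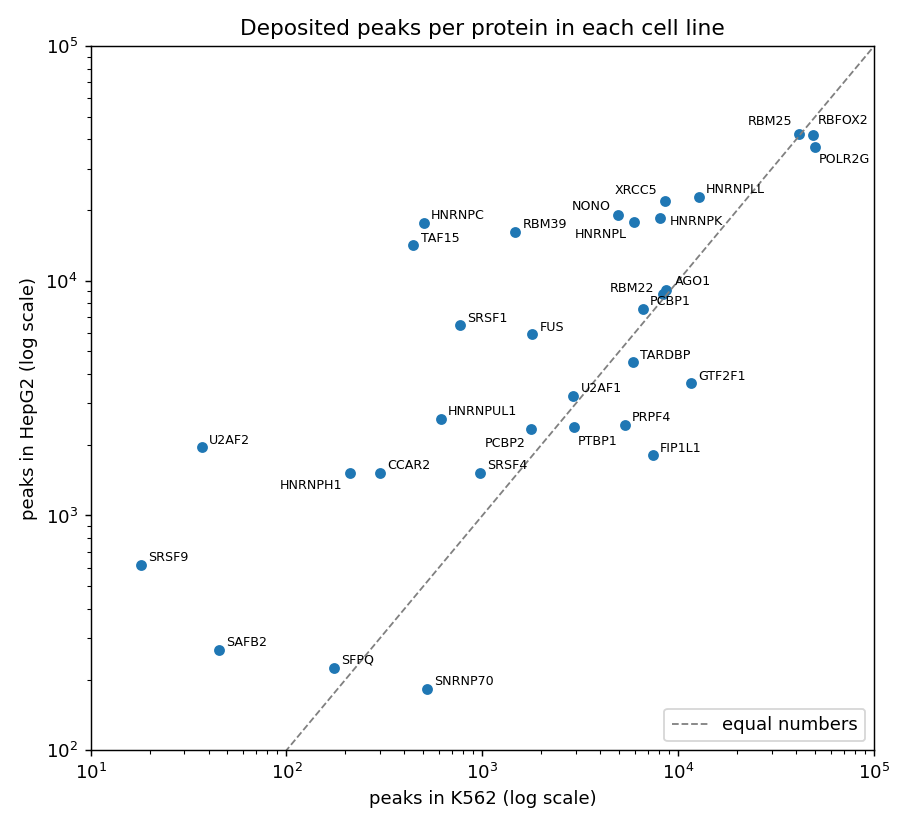
Number of deposited peaks per protein in HepG2 (y axis, log scale) against K562 (x axis, log scale), 1 point per protein with lists in both lines. The dashed line marks equal numbers; 24 of 32 points lie above it, with U2AF2 (1954 and 37) and HNRNPC (17697 and 501) far above and FIP1L1 (1803 and 7410) below.

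Peaks of most RNA-binding proteins lay where POLR2G was found in the same line. POLR2G peaks covered 0.594% of the genome in HepG2 and 0.791% in K562, yet they met over 50% of the peaks in 23 of the 32 other HepG2 lists and 26 of the 34 other K562 lists. FIP1L1 had 92.9% of its HepG2 peaks (95% interval 91.7 to 94.1) and 96% of its K562 peaks there, and NONO had 88.3% and 94.6%. PCBP2, a poly(C)-binding protein, had only 22.1% in HepG2 and 24.3% in K562, HNRNPK 32.5% and 46.2%, and SRSF9 0.647% of 618 in HepG2 (0.177 to 1.65). Several proteins stood at different shares in the lines. The spliceosomal proteins PRPF4 and RBM22 had 45.1% and 49% in HepG2 against 96% and 88.3% in K562, and HNRNPL had 49.1% against 83.7%. RBM25 went the other way, from 36.7% in HepG2 (36.3 to 37.2) to 11.4% in K562 (11.1 to 11.7), as did PTBP1 (80.8% and 49.9%) and CCAR2 (75.6% and 44.3%).

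Over 28 proteins the mean share at POLR2G sites was 68% in HepG2 (SD 19.5) and 74.1% in K562 (SD 22.1). It was 6.13 points higher in K562 (SD 19, n = 28), in 22 of 28 proteins, and did not pass the test (two-sided sign-flip permutation p = 0.098). HepG2 minus K562 was -9.48 (permutation p = 0.018) among proteins with at least 500 peaks, -2.64 (permutation p = 0.516) with lists of equal length per protein, and -29.6 (permutation p = 1.0e-05, the smallest it can give) with GTF2F1 in place of POLR2G, whose K562 list is longer. With both GTF2F1 lists at equal length it was -9.87 (permutation p = 8.1e-04), and with both POLR2G lists at equal length -4.13 (permutation p = 0.254). Without CCAR2, PTBP1 or RBM25 alone the permutation p was 0.036, 0.037 or 0.046.

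**Figure D2:**
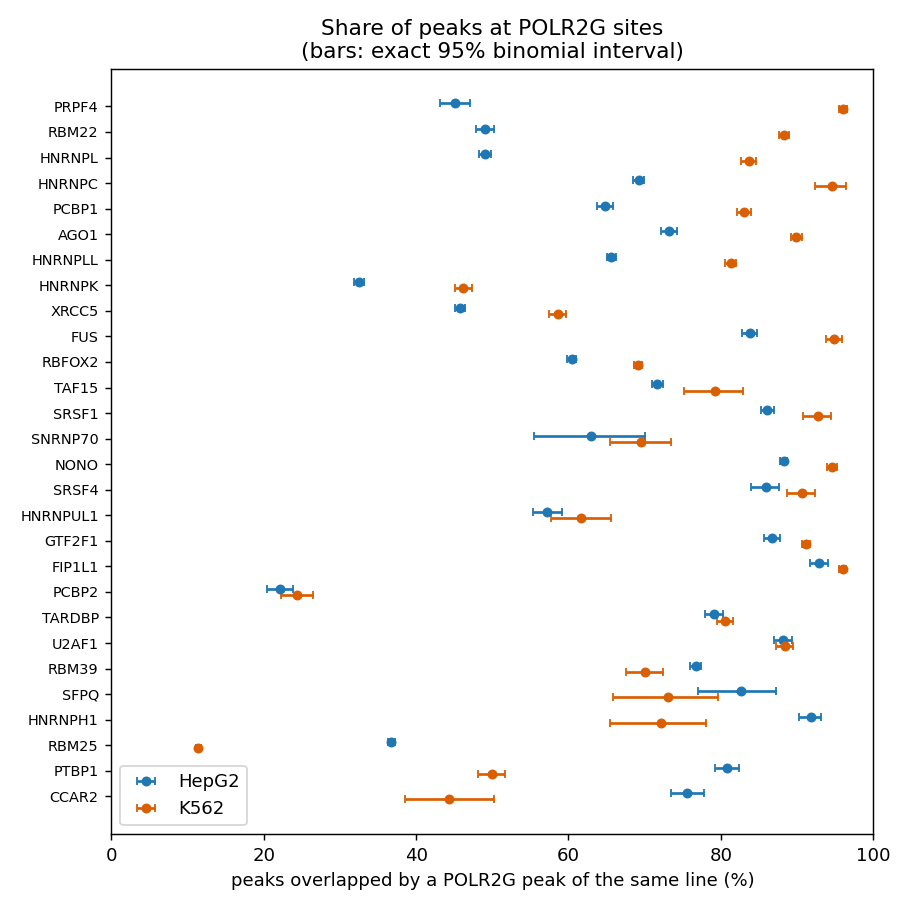
Share of each protein's peaks overlapped by a POLR2G peak of the same line (x axis, %), with exact 95% binomial intervals that cover counting error only. Of the 28 proteins 22 stand higher in K562, led by PRPF4 (45.1% and 96%), and 6 stand lower, among them RBM25, PTBP1 and CCAR2.

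A protein's list in HepG2 tended to resemble its own list in K562. NONO had a log2 odds ratio of 6.19 between its lists, HNRNPC 6.15, SRSF4 6.05, HNRNPH1 6.04 and FUS 5.89. For HNRNPC the closest K562 list was that of FUS (6.32), and the HNRNPC list ranked 3. The Ku subunit XRCC5 and PCBP2 reached 3.74 and 3.59, and in both cases no other K562 list came closer. For RBM25 the measures went different ways. Its log2 odds ratio was -0.0588 and its own K562 list ranked 28 among the 29 K562 lists, but its own HepG2 list ranked 8 among the HepG2 lists. RBM25 shared 27.1% of its HepG2 and 26.9% of its K562 peaks, where the medians over proteins were 15.8% and 33.2%, and over the regions of all 70 lists the log2 odds ratio was 0.673 (0.635 to 0.711). PTBP1 and POLR2G each ranked 23. Over 29 proteins and 127355 merged regions, lists of the same protein had a mean log2 odds ratio of 4.2 (SD 1.38, n = 29) and lists of different proteins 3.2. The difference of 1.01 was past the test (one-sided permutation of protein names, p = 1.0e-05, the smallest it can give). A protein's own list ranked 1 among the K562 lists for 10 of 29 proteins, where 1 is the number by chance, and from 15 to 28 for 7. In regions without a POLR2G peak the difference was 2.42.

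Peaks found in both lines were more frequent at POLR2G sites. Of RBFOX2 peaks in HepG2, 68.4% at POLR2G sites and 34.2% elsewhere met a K562 RBFOX2 peak. The shares were 51.5% and 20.6% for HNRNPLL, 48.9% and 20% for GTF2F1, 41.7% and 10.2% for FIP1L1, and 36% and 8.09% for TARDBP. RBM25 had 24.6% at POLR2G sites and 28.6% elsewhere, PCBP2 7.53% and 10.4%, and CCAR2 3.39% and 4.04%, the 3 proteins in which the order was reversed. Over 28 proteins the mean was 21.6% at POLR2G sites and 10.6% elsewhere, a difference of 11 points (SD 11.1, n = 28), in the same direction for 25 (two-sided sign-flip permutation p = 1.0e-05, the smallest it can give). Shared peaks also had the higher deposited signal in 26 of 28 proteins, with a mean area under the curve of 0.635 (SD 0.117), where 0.5 means no difference.

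Pairs of proteins that shared regions in one line tended to share them in the other. HNRNPH1 and SFPQ had a log2 odds ratio of 6.34 in HepG2 and 8.41 in K562, SFPQ and SNRNP70 6.18 and 6.15, NONO and RBFOX2 6.15 and 5.78, and FUS and HNRNPC 7.36 and 5.15. The first 2 of these pairs rest on short lists. SFPQ had 225 peaks in HepG2 and 175 in K562, SNRNP70 183 and 522, and HNRNPH1 1515 and 210. Of 406 pairs of 29 proteins, 374 were above 0 in both lines. Opposite signs occurred in 27 pairs, and 22 of these were pairs with RBM25, all positive in HepG2. Across the pairs, which share proteins and are not independent, Pearson's r was 0.473 (p = 2.8e-04) and Spearman's rho 0.448 (p = 2.0e-04), both two-sided permutations of protein names. Without PCBP2 and RBM22, the proteins farthest from the median in HepG2, r was 0.437 (permutation p = 0.002), and without RBM25, the farthest in K562, it was 0.477 (permutation p = 1.0e-04, the smallest it can give). These were the 2 correlations computed.

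Sharing of regions among members of one protein family did not pass the test in either line. In HepG2 the FET proteins FUS and TAF15 had a log2 odds ratio of 4.79, U2AF1 and U2AF2 4.26, and NONO and SFPQ 3.81, while the pairs of SR proteins averaged 0.341. That mean is set by SRSF9: SRSF1 and SRSF4 stood at 4.01, and SRSF9 at 0.239 with SRSF4 and -3.23 with SRSF1. In K562 the 6 pairs of SRSF1, SRSF3, SRSF4 and SRSF7, without SRSF9, averaged 5.31 against 3.52 for other pairs, an excess of 1.79 (one-sided permutation p = 0.020, adjusted p = 0.141 over the families). The RBM proteins, grouped only by name, averaged 1.14 in HepG2 and 0.222 in K562. Over all families the excess was -0.274 in HepG2 (one-sided permutation p = 0.701) and -0.029 in K562 (p = 0.557), and the difference between the lines did not pass the test either (-0.443, two-sided permutation p = 0.386). With the overlap expected from covered genome, the HepG2 excess turned to 0.133 (permutation p = 0.436).

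Many proteins gathered in the same regions. HepG2 peaks merged into 83438 regions with 3.1 proteins each on average, against 1.08 with randomly placed peaks, and K562 peaks into 82540 regions with 2.21, against 1.05. A single protein held 58.5% of the HepG2 regions and 68.5% of the K562 regions. At least 10 proteins met in 8054 HepG2 regions (9.65%) and 3309 K562 regions (4.01%), where 100 random draws gave at most 1 and 0. The draws used all positions of a chromosome, so any preference for parts of the genome that the lists share would exceed them. The most crowded regions held 31 proteins in each line. POLR2G, itself among the proteins counted, was in 96.5% of the HepG2 regions with at least 10 proteins and in 5.52% of those with a single one. In K562 these shares were 99.6% and 14.2%. A region with a single protein can hold POLR2G only where no other protein was found, so part of this contrast follows from the counting. Crowded regions were also wider, with a median of 1390 bp against 484 bp in HepG2 and 1718 bp against 360 bp in K562, which leaves more room for peaks to be merged.

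**Figure D3:**
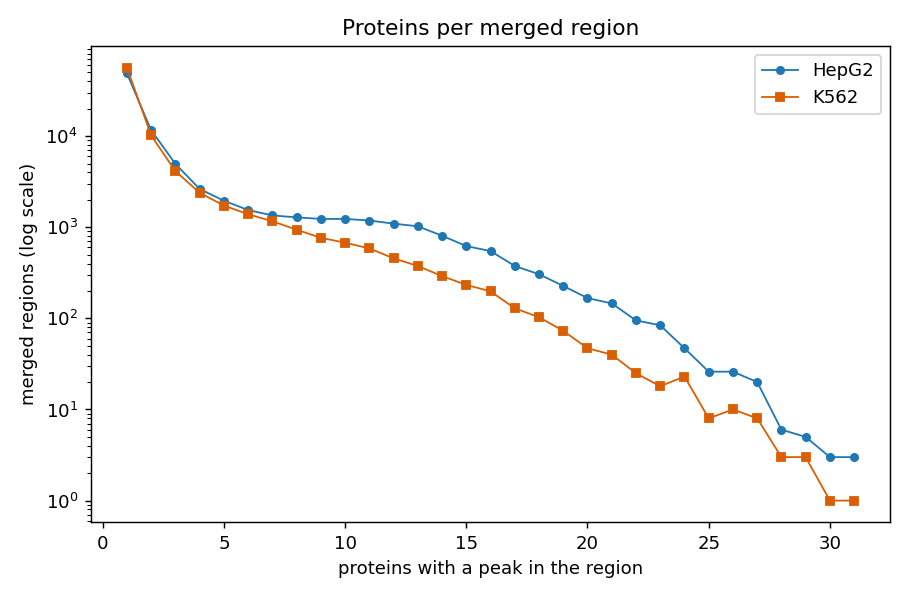
Number of merged regions (y axis, log scale) by the number of proteins with a peak in them (x axis) in HepG2 and K562. Counts fall from 48810 HepG2 and 56554 K562 regions with 1 protein, and from 2 proteins on HepG2 has more regions than K562 at every number.

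Some regions were bound by many proteins in one line and few in the other. The HepG2 region named first, on chromosome 14 from 24104709 to 24117565, was tied for the smallest adjusted p. It held 25 proteins in HepG2, among them FUS, HNRNPL, SRSF1 and U2AF1, and AGO1 and RBFOX2 in K562 in lists of equal length (exact McNemar p = 2.4e-07, adjusted p = 4.6e-04). Neighbouring regions on chromosome 17, from 79948926 to 79955696 and from 79957384 to 79960119, held 23 and 22 proteins in HepG2 and 0 in K562. The first of these neighbours had the same p and adjusted p as the chromosome 14 region. A region on chromosome 2, from 21252238 to 21267406, held 21 in HepG2, with HNRNPLL alone in K562. In K562, a region on chromosome 1 from 228643258 to 228647436 held 24 proteins, among them HNRNPC, NONO, PRPF4 and XRCC5, and 0 in HepG2 (exact McNemar p = 1.2e-07, adjusted p = 4.6e-04). On chromosome 17, from 56403276 to 56410888, 24 proteins met in K562 and AGO1 and HNRNPL in HepG2. Regions on chromosome 22 from 17081728 to 17083839 and on chromosome 7 from 106299220 to 106301958 each held 19 proteins in K562 and 0 in HepG2. The 12 regions named for HepG2 held 20 to 28 proteins there and 0 to 7 in K562, and the 12 named for K562 held 17 to 25 there and 0 to 8 in HepG2. The region with the most proteins over both lines, on chromosome 11 from 65184553 to 65208058, held 23 in HepG2 and all of these plus 4 others in K562. The next, on chromosome 6 from 30707435 to 30712762, held 28 in HepG2 and 19 in K562.

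Of 109914 regions 5829 could be tested, and 718 had more proteins in HepG2 and 362 in K562 (exact McNemar test, Benjamini-Hochberg; 2513 at an unadjusted p under 0.05). RBFOX2, RBM25 and POLR2G, the longest lists among the proteins counted, were in 97.6%, 98.3% and 96.9% of the HepG2 regions in HepG2, and in 99.2%, 67.7% and 98.6% of the K562 regions in K562. With POLR2G lists as deposited, 51.1% of the HepG2 regions had a POLR2G peak in K562 and 59.1% of the K562 regions had one in HepG2. The counts were 2485 and 194 with lists as deposited, 312 and 202 with the top 50% of each list by signal, and 529 and 443 without RBM25. On the 10 autosomes whose share of peaks did not pass the test of a difference lay 115 of the 718 and 115 of the 362 regions, and 74 and 77 were called when p was adjusted over these autosomes alone.

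Peaks were also spread differently over the autosomes. Chromosomes 2, 14 and 20 held a higher share of the peaks in HepG2 for 29 of 29 proteins, with means of 10.9%, 5.95% and 8.43% against 5.26%, 1.31% and 2.34% in K562, and chromosomes 16 and 17 were higher as well. Chromosomes 1, 5, 7, 11, 19, 21 and 22 were higher in K562, led by chromosome 1 with 13.1% against 7.29%. The shares of a list add up to a fixed total, so a higher share on some autosomes lowers the others. The autosomes higher in K562 are therefore not independent of those higher in HepG2. Chromosome 22 rested partly on a few short lists: TAF15 had 36.2% of its K562 peaks there, SNRNP70 26.2%, HNRNPUL1 17.7% and CCAR2 15.3%, against a mean of 5.96%. All 12 passed a two-sided sign-flip permutation test over 29 proteins after adjustment over 22 autosomes, with the weakest at an adjusted p of 2.7e-04. The 5 autosomes higher in HepG2 held 41.1% of the peaks of a HepG2 list on average (SD 8.94) and 20.2% of those of a K562 list (SD 2.6). They held 518 of the 718 HepG2 regions (72.1%) and 31 of the 362 K562 regions (8.56%). With lists of equal length 13 autosomes were higher in K562.

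**Figure D4:**
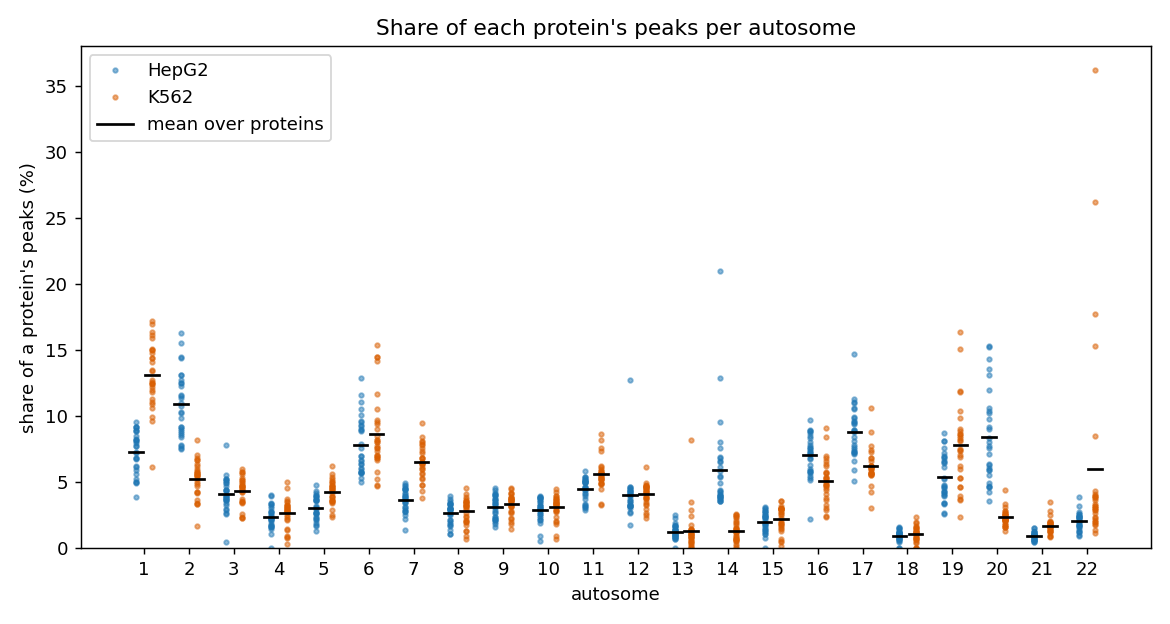
Share of each protein's peaks on each autosome (y axis, %), with 1 point per protein and line and black bars for the means over 29 proteins. HepG2 stands higher on chromosomes 2, 14 and 20 in all 29 proteins, and chromosome 1 is higher in K562 (13.1% against 7.29%).

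RBM25 and the zinc finger transcription factor YY1 were paired in the design, which profiled each with the other knocked down. Only the NC lists could be compared here. YY1 peaks met 15.1% of the RBM25 NC peaks (95% interval 14.8 to 15.4), and RBM25 NC peaks met 33.6% of the YY1 peaks (33.1 to 34.1). Randomly placed peaks gave 1.38% and 3.07%, so the overlaps were 10.9-fold and 11-fold higher. Peaks were placed anywhere on their chromosome, so a preference for the same parts of the genome would also give such folds. RBM25 NC peaks at POLR2G sites of HepG2 met YY1 in 88.5% of 7577 cases and those elsewhere in 6.35% of 63458. YY1 also met 53.5% of all POLR2G peaks of HepG2, and 79% of the NONO peaks, of which 88.3% lay at POLR2G sites. A high share at these sites was therefore not particular to RBM25. Among the regions of the HepG2 and NC lists, however, RBM25 NC and YY1 had a log2 odds ratio of -0.806, and RBM25 NC ranked 33 of 34 lists. The single-end RBM25 list of HepG2 had 1.84 with YY1 and ranked 26. The background here is regions bound in any of these lists, so the negative value does not mean less overlap than with random placement. Over the regions of all lists, K562 included, the log2 odds ratio of RBM25 NC and YY1 was -0.169. FUS came first, with 88.1% of its peaks met by YY1 and a log2 odds ratio of 5.66, ahead of HNRNPC (5.04) and NONO (5.02). The region with the smallest sum of ranks, on chromosome 17 from 47865373 to 47866940, held 15 HepG2 proteins, and all 10 such regions had a POLR2G peak. The share of 15.1% became 8.05% with reciprocal overlap of at least 50%, 5.78% with summits within 100 bp, 4.59% for peaks away from the POLR2G peaks of both lines, and 36% with the single-end RBM25 list.

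RBM25 was profiled in HepG2 in both experiments with the same antibody. The RBM25 NC list met 42% of the single-end HepG2 peaks (95% interval 41.5 to 42.4), and 24.7% of the NC peaks were met in turn, a log2 odds ratio of 0.466 (0.432 to 0.5). The K562 list of RBM25 stood closer to the NC list, with 64.1% of its peaks met (63.6 to 64.6) and a log2 odds ratio of 1.96 (1.93 to 2). Regions with a peak in the RBM25 K562 and NC lists but not in the single-end HepG2 list numbered 15789. Of these, 0.652% had a POLR2G peak in HepG2 and 94.1% had no protein other than RBM25 and POLR2G. The 17829 regions found in the single-end HepG2 list alone had a POLR2G peak in 30.6%.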

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

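Chosen after the result was seen were the tests of K562 material, of a list made wholly from K562 cells, of the paired-end experiment and of a mapping error in the K562 windows. The readings of the tests of extra copies, amplified DNA, K562 material and mapping error were changed after their results. The crowded windows and the favoured autosomes were picked from the same lists they are tested on.

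Among regions bound by any profiled protein, those with an RBM25 peak had a POLR2G peak more often than the other regions in HepG2 and less often in K562: the log2 odds ratio was 1.43 (1.38 to 1.47) in HepG2 and -3.36 (-3.41 to -3.31) in K562, a difference of 4.79. Against the genome it still met POLR2G often in K562, in 11.4% of its peaks where POLR2G peaks cover 0.791%, and 83.9% of its K562 regions held no other protein. U2AF2 moved the same way, from 3.08 (2.93 to 3.24) to -3.62 (-5.98 to -1.26), a difference of 6.7, but its K562 list holds 37 peaks. SAFB2 also changed sign, from 2.39 in HepG2 to -0.618 in K562, with 45 peaks in its K562 list. None of these differences was tested across replicates, because each list stands alone.

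The RBM25 NC list, from HepG2, was closer to the K562 list of RBM25 than to the single-end HepG2 list. RNA polymerase II sites in the single-end list would have brought the gap in log2 odds ratio under 0.5 in regions without POLR2G, but it was 1.57 there (1.43 to 1.7). RBM25 NC had 244 and YY1 NC 105 peaks in 26 windows of 1 Mb where HepG2 lists had peaks and no K562 list did. These windows were picked for the lack of K562 peaks, and the RBM25 NC list is longer than the K562 list. YY1 has no K562 list here. The peaks therefore do not settle whether either list was made wholly from K562 cells. Some K562 material cannot be told apart either, because a mixture would keep these peaks. A difference between the single-end and the paired-end experiment may account for the pattern. The YY1 NC list too had only 22.6% of its peaks on the autosomes favoured by HepG2, below the lowest single-end HepG2 list (27.7%). Such shares tended to be higher in short HepG2 lists. On chromosome 20, SFPQ had 15.2% of 224 distinct intervals and POLR2G 4.62% of 25440, although SNRNP70 had 4.97% of 181. The NC lists held 71035 (RBM25) and 36826 (YY1), and lengths were not made equal here, so part of the low shares may follow from length. Both NC lists (21.5% for RBM25) lay within the range of the K562 lists there (mean 20.2%, highest 24.1%). The share of a list without any preference for these autosomes was not set beside them, so such a value is no mark of K562 cells. RBM25 NC also lay below both the K562 list (22.3%) and the single-end HepG2 list (32.2%) of RBM25. These shares therefore do not decide on K562 material, and a change of RBM25 binding between cultures was not tested.

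Short lists were crowded into a few windows of 1 Mb. SRSF9 in HepG2 had 102 of 618 peaks in 11 windows, mostly on chromosome 14, and SRSF9, U2AF2 and SAFB2 in K562 had 44 of 100 in 5 windows on chromosomes 13 and 22. A mapping error common to every list of the build would have put over 20% of these peaks on a peak of the other line, but 3.92% (1.08 to 9.74) of the SRSF9 peaks in HepG2 and 2.27% (0.0575 to 12) of the K562 peaks met one. For amplified DNA, the condition written beforehand was met: in 64 other lists the 25% of peaks with the lowest signal lay in these windows more often than the 25% with the highest, with a mean log2 ratio of 0.785 (SD 1.77, sign-flip permutation p = 8.5e-04), although 22 lists went the other way. Extra DNA adds reads to strong and weak peaks alike, so the sign of this ratio decides nothing and amplified DNA cannot be told apart from binding that differs between the lines, of which no test was made.

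Peaks gathered on different autosomes in each line. Transcription that differs between the lines would have left peaks away from POLR2G nearly even, but there HepG2 stood 35.7 points higher (SD 16.7, 28 of 28 proteins, sign-flip permutation p = 1.0e-05, the smallest it can give). Among peaks at POLR2G sites of either line HepG2 stood 18.3 points higher (SD 9.57, n = 29). For extra copies of chromosomes, the condition written beforehand against them was met: the 25% of HepG2 peaks with the lowest signal lay on these autosomes less often than the 25% with the highest, by -2.59 points (SD 7.12, n = 33, sign-flip permutation p = 0.044). It was set aside for the same reason as in the crowded windows, and because the 25% with the lowest signal still had 43.2% there against at most 24.1% in a K562 list. The NC lists labelled HepG2 had only 21.5% and 22.6% there. They come from another experiment and were not cut to the length of the other lists. A property of all HepG2 chromosomes is therefore not decided by them. Without read depth, extra copies cannot be told apart from other differences.

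For the regions bound by more proteins in one line, the line names were exchanged at random within proteins. As many as the real 1080 regions came in 1 of 100 assignments, the real one, and the highest of the others was 0. This goes against differences that arise by chance in each protein separately. The exchange also breaks up whatever all lists of a line have in common. It therefore cannot exclude a chance difference shared by the lists of a line.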

How the results depend on the processing

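Chosen after seeing the data were all alternatives for the POLR2G share, the shared peaks, the regions and the autosomes, those without POLR2G peaks, and, for the number of peaks, distinct intervals and lists of the same kind. Of 57 alternatives other than leaving out a protein, 40 kept direction and side of the threshold, stayed within the counting interval, or, for counts, stayed within 1.5 times. For the others the cause was not tested, except where stated.

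The POLR2G share was past the threshold at -9.48 with at least 500 peaks, at -29.6 with GTF2F1 in place of POLR2G, whose lists differ in length, and at -9.87 with GTF2F1 lists of equal length; with POLR2G lists of equal length it stayed short of it at -4.13. The family excess in HepG2 turned from -0.274 to 0.133 with overlap expected from covered genome. RBM25 NC peaks met by YY1 went from 15.1% to 8.05% (reciprocal overlap), 5.78% (summits within 100 bp), 15.7% (top 50% by signal), 4.59% (away from POLR2G of both lines) and 36% (single-end RBM25 list). RBM25 single-end against paired-end went from 42% to 35.5% with summits. HepG2 regions went from 718 to 2485 (lists as deposited), 74 (p adjusted over the 10 autosomes without a difference in peak share alone, where the main test had 115 for each line) and 312 (top 50%), and K562 regions from 362 to 194, 77 and 202. Autosomes higher in K562 went from 7 to 13 with lists of equal length.

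Leaving out 1 protein at a time gave 1.11 to 1.36 for the log2 ratio of peaks, -7.52 to -4.47 for the POLR2G share, 0.903 to 1.06 for the same protein, 10.1 to 11.6 for shared peaks, 0.418 to 0.512 for pairs, 529 to 718 HepG2 regions and 288 to 443 K562 regions, with 529 and 443 both reached without RBM25. Of these 210 settings 207 changed no call, and the share passed the threshold without CCAR2, PTBP1 or RBM25. No paired analysis was possible because each analysed list is the only one of its protein, line and experiment, so there were no replicate values to pair. This concerns replicates only, and tests between the lines were paired by protein. Not run for lack of an hg19 annotation or genome were all alternatives for promoters, gene lists and the YY1 motif, and those with regions outside promoters. Read depth is unknown, and precision is lowest for the 3 HepG2 and 8 K562 lists with under 500 peaks.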

Other observations

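Among the tests on HNRNPK and on the RBM25 lists reported here, the tests of mislabelled lists were chosen after the result was seen, and the reading of the supplier test was changed after its result.

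HNRNPK and the poly(C)-binding proteins PCBP1 and PCBP2, which share KH domains, shared regions more than the median pair away from POLR2G, but over all regions only HNRNPK and PCBP2 in K562 stood clearly above it. The log2 odds ratio in K562 was 5.52 between HNRNPK and PCBP2, 3.82 between HNRNPK and PCBP1, and 3.54 between PCBP1 and PCBP2, where the median pair had 3.75. HNRNPK met 76.7% of the PCBP2 peaks in K562 and 53.9% in HepG2. In HepG2 the pairs stood at 2.79, 2.78 and 2.8, below the median of all pairs (3.11). In regions without a POLR2G peak, where the median pair had 1.31 in HepG2 and 1.53 in K562, the pairs reached 2.69 to 5.64. RNA polymerase II sites would have brought the lowest of them under 1, but it was 2.69. A shared antibody supplier would have needed an excess of at least 1 among same-supplier pairs of other proteins in both lines. It was 0.258 in HepG2 (-0.562 to 1.01), where the upper bound just passes 1, and -0.0967 in K562 (-0.85 to 0.643), which argues against it.

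RBM25 mostly stood alone in K562. There 83.9% of the regions with an RBM25 peak held no other protein, against 39.8% in HepG2. The list closest to RBM25 NC was PTBP1 in K562 (2.13), followed by RBM25 in K562 (1.96), while single-end RBM25 in HepG2 ranked 33.

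Further tests of the RBM25 lists were these. With the lists at equal length of 41381 peaks, the gap in log2 odds ratio was 1.3 (1.16 to 1.41), above the bound of 1 written beforehand, which argues against list length as the cause. A wrong cell line on 1 of the RBM25 lists was tested in windows of 1 Mb without K562 peaks of other proteins, where RBM25 NC had 420 peaks, the HepG2 list 136 and the K562 list 60. The condition as written counted more than 5 peaks of the K562 list there as a sign of a wrong label, and 60 met it. It was set aside afterwards, because windows empty of other proteins' K562 peaks can still hold RBM25 peaks of K562 cells, so with these peaks a wrong label cannot be told apart from RBM25 binding in K562 cells. RBM25 NC had 244 peaks where no K562 list had any. Those windows were picked for having no K562 peak, of RBM25 or any other protein, and the NC list is longer than the K562 list. A K562 origin of the NC list as a whole is therefore not settled by these peaks. The single-end HepG2 list had 32.2% of its peaks on the autosomes favoured by HepG2, above every K562 list (at most 24.1%). That argues against a K562 origin of the single-end list as a whole. The K562 list, with 22.3% on these autosomes, lay below the lowest single-end HepG2 list (27.7%), but so did RBM25 NC (21.5%), so a HepG2 origin of the K562 list cannot be told apart.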
